A study of Homo sapiens with 8 samples.

How the data were processed

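The series measured A549 lung adenocarcinoma cells with a short hairpin against FKBP10 and control cells of the same line. Ribosome-protected fragments and RNA were each sequenced from 2 control and 2 knockdown libraries, 8 libraries in 4 groups. Per the labels, cells were collected near confluence, lysates were treated with 1.65 units of RNase I, and monosomes were taken from a sucrose gradient before the footprint libraries were made. Groups and replicate numbers were taken from the sample titles. The titles of the knockdown libraries end in SH1 and SH2 and do not say whether both carry the same hairpin. The source name in the labels reads control for all 8 samples, so the titles were checked against the counts of FKBP10, which are given first in the results.

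The submitters' processing notes name HISAT2, Bowtie2 and edgeR and the builds GRCh38 and hg38, without versions and without saying what each was used for. The deposited table holds 20346 genes with 1 Ensembl transcript each, and per the file headers 8 of its columns are counts. The values of these deposited count columns are whole numbers whose totals differ between libraries. The other 8 columns are RPKM per the file headers, with the footprint columns headed PPKM. Each deposited RPKM value equals the count divided by the column total and by 1 length per transcript, with a largest relative spread of 4.88e-14 between libraries. That length equals the coding length in GENCODE release 29 plus 3 bases for 15559 of the 16573 transcripts for which it could be computed, so the values are per kilobase of coding sequence. RPKM was used only in 1 alternative for the correlation of fold changes. Transcripts were matched to GENCODE by transcript identifier (19208) or by symbol (961), and 177 stayed unmatched. No column was left out. Only this table was analysed here.

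The notes used here state no rule for reads that match several genes and no strand setting. Values for near-identical genes are therefore uncertain, among them SERPINB3 and SERPINB4, the NOMO genes, replication-dependent histones, ferritin and ribosomal protein genes with many pseudogenes, and MTRNR2L8. The same holds for overlapping genes such as CFB and the readthrough transcript XXbac-BPG116M5.17.

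Footprint libraries held 9354686 and 7985713 counts in controls and 1645405 and 6105162 in knockdown cells. RNA libraries held 28550875 and 23684143 counts in controls and 16793696 and 20997674 in knockdown cells. At the lowest depth, in the first knockdown footprint library, 3 counts correspond to 1.82 CPM, counts per library total of 1e6, against 0.32 to 0.49 in the other footprint libraries and 0.11 to 0.18 in the RNA libraries. No pair of count columns was identical. The chi-square per degree of freedom between replicates was 2.35 and 5.25 for control and knockdown footprints. It was 11.7 and 8.11 for control and knockdown RNA. So the replicates differ by more than repeated sequencing of 1 library would give. A large part of the value for knockdown footprints comes from 1 gene, MTRNR2L8, with 10468 and 275 counts in these libraries.

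Knockdown was compared with control in RNA and in footprints by separate fits of 4 libraries each. The change in translational efficiency, footprints over RNA, was the interaction contrast in 1 group-means model over all 8 libraries. All of these used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with robust estimates, TMM scaling, the default filterByExpr filter (minimum count 10, total 15) within each kind of library, and Benjamini-Hochberg adjustment over the genes tested. A gene is said to have risen, fallen or changed at an adjusted p under 0.05, with no minimum fold. Standard errors are the size of the log2 fold change divided by the root of the quasi-likelihood F statistic. Gene lists were tested with camera in limma 3.58.1 with its preset correlation of 0.01 between genes and again with a correlation estimated from the data, with Benjamini-Hochberg adjustment over the lists of at least 5 tested members in each comparison. With an estimated correlation camera rests on the few residual degrees of freedom of each fit, so p-values rise even where the estimate is under the preset. The 30 lists hold 975 members, of which 973 are in the table. Counts of list members were made with adjustment over all genes tested and again with adjustment over the list alone.

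The main tests, the lists, the rule for naming genes and most alternatives were fixed before the data were examined, and those added later are named in the closing section. The rule takes, per comparison, the 10 largest rises and 10 largest falls among genes that passed, whose libraries do not overlap between groups and whose mean count is at least 50, and then up to 4 members of each list with the smallest p-values. Proline content was taken from the GENCODE coding sequences with Biopython 1.88 under Python 3.11.15 and pandas 2.3.3, as the presence of 3 prolines in a row and as the share of proline codons. Hydropathy of the encoded proteins (Kyte-Doolittle scale) was added after the results had been seen, with a window of 9 residues within the first 35 and a threshold of 2 for the N-terminus, and a window of 19 residues and a threshold of 1.6 for internal segments. Figures were drawn with matplotlib 3.10.9.

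Alternatives were DESeq2 size factors and library totals in place of TMM, no filter, a mean count of 50, DESeq2 1.42.0, limma-voom, a fit of all 8 libraries for the RNA and footprint contrasts, a replicate block, and each library left out in turn. Where a group is left with 1 library, that library is assumed to vary like those of the other groups. The fits were tested on simulated data with 200 changed genes. At a log2 fold change of 1, 73% of 100 changed genes were recovered in RNA, 82% in footprints and 64% in translational efficiency. At a log2 fold change of 2, 96%, 98% and 94% were recovered. False calls were 8 of 12906 genes, 5 of 11328 and 3 of 11224. The simulated counts followed the dispersion trend of each fit, without spread of single genes around it and without outlying libraries. The real data hold more changes, and mostly smaller ones, so these rates test the fits and do not measure their performance on the real data. Nothing in the labels says that the replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical.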

Results

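A549 cells, a human lung adenocarcinoma line, were either controls or carried a short hairpin against FKBP10, a prolyl isomerase of the endoplasmic reticulum (ER) that assists the folding of collagens. Ribosome footprints and RNA were sequenced in 2 control and 2 knockdown libraries each. The question addressed is how the RNA of each gene, its ribosome footprints and the ratio of these, its translational efficiency, differ when FKBP10 is reduced. Each footprint library had a count for 12504 to 13486 genes and each RNA library for 14606 to 15244. The 20 most abundant genes took 11.1% to 12.5% of counts in every library. Replicates correlated at 0.981 to 0.995 (Pearson, log2 CPM) and libraries of different groups at 0.961 to 0.973 in footprints and 0.975 to 0.977 in RNA. The first principal component, 72.4% of the variance in RNA and 70.9% in footprints, separated knockdown from control in both. The second, 15.69% in RNA and 21.35% in footprints, set the 2 knockdown libraries apart from each other, while the controls lay close together. Genes of the mitochondrial genome took 3.85% to 4.39% of RNA counts and 0.000475% to 0.00328% of footprint counts.

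FKBP10 was lower in both knockdown libraries than in both controls, in RNA and in footprints. RNA counts were 1662 and 1278 in controls (58.2 and 54.0 CPM, counts scaled by the library total) and 347 and 510 in knockdown cells (20.7 and 24.3 CPM). Footprint counts were 405 and 323 in controls (43.3 and 40.4 CPM) and 36 and 102 in knockdown cells (21.9 and 16.7 CPM). FKBP10 RNA fell by 1.31 on the log2 scale (standard error 0.12, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 2.47e-10), leaving 40.4% of the control level. Its footprints fell by 1.25 (standard error 0.16, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 1.42e-07), leaving 42.0%. Footprints of FKBP10 over its RNA did not pass the test, at a log2 fold change of 0.09 (95% interval -0.31 to 0.49, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.915). That small value changes sign without footprint control replicate 2 (-0.04), footprint knockdown replicate 1 (-0.13) or RNA knockdown replicate 1 (-0.02). The counts belong to transcript ENST00000321562.8 of gene ENSG00000141756.18 on the plus strand of chromosome 17, from 41812680 to 41823217 in GRCh38, with 10 coding exons.

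**Figure D1:**
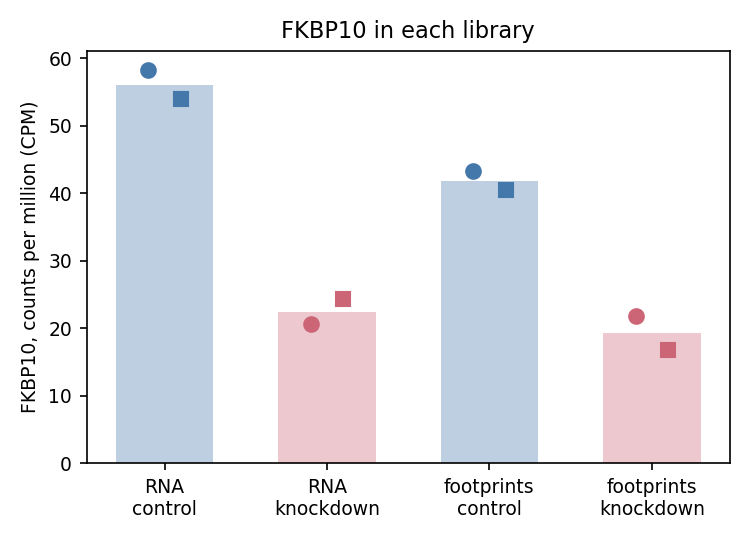
FKBP10 in each library, in CPM, for RNA and for ribosome footprints. Each point is 1 library and each bar the mean of a group.

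The largest changes in RNA are given first, among genes with a mean count of at least 50. Values after gene names are log2 fold changes of knockdown over control with their standard errors, and n is 2 libraries against 2 throughout. The protease inhibitors SERPINB3 (5.05 ± 0.31) and SERPINB4 (4.63 ± 0.46) rose most together with HSD11B1 (4.85 ± 0.33), which makes active glucocorticoid from its inactive form. USH1C (3.53 ± 0.16), which encodes the scaffold protein harmonin, rose from a mean of 5.15 to 58.7 CPM. EGR1 (-2.42 ± 0.34), an immediate early transcription factor, and DRD1 (-2.43 ± 0.39), a dopamine receptor, fell most.

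Also among the 10 largest rises of RNA were CEACAM5 (4.14 ± 0.31), a cell-surface carcinoembryonic antigen, LCN2 (3.57 ± 0.26), a lipocalin that binds iron-siderophore complexes, and CFB (3.49 ± 0.30), a complement factor. SLC17A3 (3.44 ± 0.39), an organic anion transporter, and CA9 (3.38 ± 0.20), a carbonic anhydrase induced by hypoxia, completed them, with XXbac-BPG116M5.17 (3.49 ± 0.33), which shares exons with CFB and is not independent of it. SERPINB3 and SERPINB4 lie side by side on chromosome 18, from 63655197 to 63661963 and from 63637259 to 63644298, and are similar enough to share reads, so each value is uncertain. Falls were found for the cation channel TRPA1 (-2.15 ± 0.19), the adhesion protein KIRREL3 (-1.99 ± 0.40), ANKRD1 (-1.98 ± 0.22), a target of YAP signalling, and TMPRSS15 (-1.79 ± 0.23), the protease enteropeptidase. KCNF1 (-1.62 ± 0.28), a potassium channel subunit, PDE3B (-1.61 ± 0.25), a cyclic nucleotide phosphodiesterase, and FAM129A (-1.57 ± 0.24) also fell. HAPLN3 (-1.75 ± 0.41), a hyaluronan link protein, fell too, but its value moved to -2.95 without RNA knockdown replicate 2, to -1.17 without RNA knockdown replicate 1 and to -1.50 without RNA control replicate 1, where the call was lost (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.133).

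By the edgeR quasi-likelihood test, 2656 of 12906 genes changed in RNA, 1554 higher and 1102 lower, and 4204 had an unadjusted p under 0.05. Changes of more than 2-fold were 534 upward and 75 downward, and the median size of a change was 0.55 on the log2 scale. The number fell to 1280 without RNA control replicate 1 and to 1346 without RNA control replicate 2. In 1 fit over all 8 libraries the split was 1554 higher and 1931 lower.

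The interferon response genes rose as a group in RNA. Of 42 tested, 27 rose, 0 fell and 15 did not pass, or 32 and 1 adjusted over the list alone. The group's median was 0.80 (camera, Benjamini-Hochberg adjusted p = 1.99e-13, and adjusted p = 0.205 with an estimated correlation). SAMD9L (2.11 ± 0.21), an antiviral factor, IFIT1 (1.36 ± 0.17), which binds viral RNA, and PARP9 (1.45 ± 0.13) are examples. The glycolysis and hypoxia-responsive genes, 35 tested, had 18 that rose, 0 that fell and 17 that did not pass, or 19 and 1 adjusted over the list alone. The median was 0.51 (camera, Benjamini-Hochberg adjusted p = 5.09e-11, and adjusted p = 0.205 with an estimated correlation). Beside CA9 these include the carbonic anhydrase CA12 (1.23 ± 0.09), NDRG1 (1.58 ± 0.12) and the mitophagy receptor BNIP3L (0.86 ± 0.11). Of 24 epithelial junction and keratin genes 11 rose, 2 fell and 11 did not pass, or 12 and 2 adjusted over the list alone, such as E-cadherin CDH1 (1.23 ± 0.09) and the keratins KRT18 (0.92 ± 0.09) and KRT8 (0.90 ± 0.09). Their median was 0.65 (camera, Benjamini-Hochberg adjusted p = 2.39e-08, and adjusted p = 0.205 with an estimated correlation).

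Of the genes of collagens and the extracellular matrix 14 of 33 rose, with 1 that fell and 18 that did not pass, or 18 and 1 adjusted over the list alone. The list median was 0.37 (camera, Benjamini-Hochberg adjusted p = 2.34e-05, and adjusted p = 0.279 with an estimated correlation). Fibronectin FN1 (1.65 ± 0.10), the basement membrane collagen COL4A4 (1.67 ± 0.16) and the laminin chain LAMB3 (1.56 ± 0.16) rose, and thrombospondin THBS1 (-1.12 ± 0.12) fell. Of 25 inflammatory and NF-kB targets 11 rose, 6 fell and 8 did not pass, or 11 and 7 adjusted over the list alone. The list had a median of 0.62 (camera, Benjamini-Hochberg adjusted p = 5.29e-04, and adjusted p = 0.279 with an estimated correlation). Complement C3 (1.25 ± 0.09) and the mitochondrial dismutase SOD2 (0.92 ± 0.10) rose and the cytokine IL6 (-1.12 ± 0.12) fell. Among 34 NRF2 targets 16 rose, 3 fell and 15 did not pass, with the same counts of 16 and 3 adjusted over the list alone, led by the aldehyde dehydrogenases ALDH3A1 (1.33 ± 0.09) and ALDH1A1 (1.09 ± 0.09) and heme oxygenase HMOX1 (1.19 ± 0.10). The members had a median of 0.18 (camera, Benjamini-Hochberg adjusted p = 9.29e-05, and adjusted p = 0.248 with an estimated correlation). The 11 alveolar and airway genes had 5 that rose, 1 that fell and 5 that did not pass, or 6 and 1 adjusted over the list alone. The median over the list was 0.23 (camera, Benjamini-Hochberg adjusted p = 0.0345, and adjusted p = 0.443 with an estimated correlation), and the call was lost without RNA control replicate 1 (adjusted p = 0.0621) or RNA knockdown replicate 2 (adjusted p = 0.102). The mucin MUC5AC (0.57 ± 0.09) rose and the transcription factor ETV5 (-0.84 ± 0.13) fell.

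Lists of genes for making ribosomes, charging tRNAs and supplying amino acids lay lower in RNA, with many members not passing. Of 38 ribosome biogenesis genes 0 rose, 20 fell and 18 did not pass, or 0 and 22 adjusted over the list alone, such as the helicase DDX21 (-0.63 ± 0.09) and NOP56 (-0.53 ± 0.09). These genes had a median of -0.29 (camera, Benjamini-Hochberg adjusted p = 5.82e-09, and adjusted p = 0.205 with an estimated correlation). Of 23 aminoacyl-tRNA synthetases and their partners 0 rose, 14 fell and 9 did not pass, or 0 and 16 adjusted over the list alone, among them MARS (-0.58 ± 0.09) and GARS (-0.56 ± 0.09). The median was -0.30 (camera, Benjamini-Hochberg adjusted p = 2.71e-06, and adjusted p = 0.209 with an estimated correlation). The ATF4 and integrated stress response targets had 3 that rose, 13 that fell and 17 that did not pass, or 4 and 17 adjusted over the list alone. Their median was -0.23 (camera, Benjamini-Hochberg adjusted p = 1.44e-04, and adjusted p = 0.209 with an estimated correlation). Asparagine synthetase ASNS (-1.03 ± 0.12), the serine pathway enzyme PSAT1 (-0.92 ± 0.11) and the folate enzyme MTHFD2 (-0.76 ± 0.09) fell and DDIT4 (0.91 ± 0.11), an inhibitor of mTORC1, rose. Cytosolic ribosomal proteins took 9.02% and 8.99% of RNA counts in controls and 8.03% and 8.05% in knockdown cells. Of 76 tested 1 rose, 17 fell and 58 did not pass, or 1 and 19 adjusted over the list alone, RPL30 (-0.52 ± 0.09) falling and RPL28 (0.49 ± 0.09) rising. The list median was -0.17 (camera, Benjamini-Hochberg adjusted p = 5.4e-06, and adjusted p = 0.279 with an estimated correlation). Of 53 translation factors 2 rose, 9 fell and 42 did not pass, also 2 and 9 adjusted over the list alone, such as the termination factor ETF1 (-0.39 ± 0.09). The list had a median of -0.12 (camera, Benjamini-Hochberg adjusted p = 0.00816, and adjusted p = 0.421 with an estimated correlation).

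Lists of sterol and cell cycle genes lay lower in RNA, with many members not passing. Of 26 cholesterol synthesis genes and SREBP2 targets 0 rose, 12 fell and 14 did not pass, or 0 and 15 adjusted over the list alone, including DHCR7 (-0.96 ± 0.16), which makes cholesterol in its last step. The members had a median of -0.37 (camera, Benjamini-Hochberg adjusted p = 3.78e-05, and adjusted p = 0.4 with an estimated correlation). Of 44 DNA replication genes 0 rose, 10 fell and 34 did not pass, or 0 and 11 adjusted over the list alone, such as MCM10 (-0.36 ± 0.09). The median over the list was -0.14 (camera, Benjamini-Hochberg adjusted p = 4.93e-04, and adjusted p = 0.209 with an estimated correlation). Of 44 mitosis genes 3 rose, 14 fell and 27 did not pass, or 3 and 15 adjusted over the list alone, with the mitotic kinase AURKA (-0.67 ± 0.09) and the CDK partner CKS1B (-0.50 ± 0.10). These genes had a median of -0.14 (camera, Benjamini-Hochberg adjusted p = 8.68e-04, and adjusted p = 0.443 with an estimated correlation). Replication-dependent histones, which share sequence, had 0 that rose, 9 that fell and 9 that did not pass of 18, or 0 and 10 adjusted over the list alone. The median was -0.31 (camera, Benjamini-Hochberg adjusted p = 3.78e-05, and adjusted p = 0.443 with an estimated correlation). Of 31 proteasome subunits 1 rose, 3 fell and 27 did not pass, or 1 and 2 adjusted over the list alone. Their median was -0.07 (camera, Benjamini-Hochberg adjusted p = 0.0136, and adjusted p = 0.331 with an estimated correlation), and the call was lost without RNA knockdown replicate 2 (adjusted p = 0.0974). The alpha subunit PSMA6 (-1.47 ± 0.10) fell by far more than the catalytic subunit PSMB5 (-0.39 ± 0.09).

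In footprints, lipocalin LCN2 (4.11 ± 0.27) and CA9 (3.78 ± 0.20) rose most among genes with enough counts, followed by CIDEC (3.49 ± 0.19), a lipid droplet protein, and TM4SF20 (3.39 ± 0.12), a membrane protein with several spans. EGR1 (-3.14 ± 0.37), TRPA1 (-1.83 ± 0.26) and KLF2 (-1.75 ± 0.26), a transcription factor, fell most. The value of KLF2 moved to -1.11 without footprint knockdown replicate 2.

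Further footprint rises were TRIM31 (3.10 ± 0.14), a ubiquitin ligase, USH1C (2.97 ± 0.19), CEACAM6 (2.86 ± 0.12), the transmembrane mucin MUC13 (2.76 ± 0.20), the apolipoprotein APOL1 (2.73 ± 0.12) and CLDN2 (2.51 ± 0.10). Falls were found for PSMA6 (-1.34 ± 0.09), the branched-chain aminotransferase BCAT1 (-1.29 ± 0.13), inositol synthase ISYNA1 (-1.26 ± 0.25), the mitochondrial carboxykinase PCK2 (-1.24 ± 0.12) and CTGF (-1.15 ± 0.22), a matricellular growth factor and YAP target. SMIM13 (-1.35 ± 0.26), a small membrane protein, fell in footprints, and its RNA value of 0.18 did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.831). By the edgeR quasi-likelihood test 2998 of 11328 genes changed in footprints, 1578 higher and 1420 lower, with 437 rises and 68 falls of more than 2-fold, a median size of 0.51 and 4185 genes at an unadjusted p under 0.05. DESeq2 called 1372, and the number fell to 1943 without footprint control replicate 1, 1772 without footprint control replicate 2 and 1716 without footprint knockdown replicate 2.

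Ribosomal proteins fell almost throughout in footprints. They took 7.62% and 7.88% of footprint counts in controls and 6.15% and 6.21% in knockdown cells. Of 74 tested 0 rose, 65 fell and 9 did not pass, the same 65 adjusted over the list alone. Ribosomal proteins had a median of -0.36 (camera, Benjamini-Hochberg adjusted p = 2.88e-18, and adjusted p = 0.216 with an estimated correlation). RPLP1 (-0.70 ± 0.07), a stalk protein of the large subunit, and RPS27 (-0.79 ± 0.08) and RPS13 (-0.63 ± 0.07) of the small subunit are examples. Of 51 translation factors 0 rose, 33 fell and 18 did not pass, or 0 and 34 adjusted over the list alone, among them the elongation factors EEF1A1 (-0.46 ± 0.05) and EEF1G (-0.52 ± 0.07). The list had a median of -0.31 (camera, Benjamini-Hochberg adjusted p = 1.5e-10, and adjusted p = 0.179 with an estimated correlation). Ribosome biogenesis genes had 0 that rose, 29 that fell and 7 that did not pass of 36, or 0 and 30 adjusted over the list alone, with DDX21 (-0.87 ± 0.08) and the nucleolar proteins NPM1 (-0.51 ± 0.06) and NCL (-0.45 ± 0.06). The members had a median of -0.38 (camera, Benjamini-Hochberg adjusted p = 1.2e-12, and adjusted p = 0.216 with an estimated correlation). Of 23 aminoacyl-tRNA synthetases and partners 0 rose, 19 fell and 4 did not pass, or 0 and 21 adjusted over the list alone, such as GARS (-0.70 ± 0.07) and EPRS (-0.59 ± 0.07), the latter charging tRNAs with glutamate and proline. The median over the list was -0.33 (camera, Benjamini-Hochberg adjusted p = 1.7e-10, and adjusted p = 0.17 with an estimated correlation). ATF4 targets had 3 that rose, 15 that fell and 14 that did not pass of 32, or 5 and 17 adjusted over the list alone, with PSAT1 (-1.04 ± 0.07), ASNS (-0.95 ± 0.08) and the amino acid transporter SLC38A2 (-0.72 ± 0.08). These genes had a median of -0.31 (camera, Benjamini-Hochberg adjusted p = 3.14e-05, and adjusted p = 0.293 with an estimated correlation). With DESeq2 9 ATF4 targets fell and 2 rose.

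Of 44 DNA replication genes 0 rose in footprints, 26 fell and 18 did not pass, or 34 fell adjusted over the list alone, such as thymidylate synthase TYMS (-0.60 ± 0.07) and the helicase subunit MCM5 (-0.42 ± 0.08). The median was -0.30 (camera, Benjamini-Hochberg adjusted p = 6.89e-09, and adjusted p = 0.216 with an estimated correlation). Of 44 mitosis genes 1 rose, 27 fell and 16 did not pass, or 1 and 28 adjusted over the list alone, with AURKA (-0.77 ± 0.08) and CDK1 (-0.45 ± 0.07). Their median was -0.25 (camera, Benjamini-Hochberg adjusted p = 1.06e-07, and adjusted p = 0.216 with an estimated correlation). Histones had 0 that rose, 15 that fell and 4 that did not pass of 19, or 0 and 16 adjusted over the list alone. The list median was -0.31 (camera, Benjamini-Hochberg adjusted p = 9.36e-07, and adjusted p = 0.344 with an estimated correlation). Of 22 cytosolic heat shock proteins 2 rose, 13 fell and 7 did not pass, also 2 and 13 adjusted over the list alone, such as HSPA8 (-0.45 ± 0.05) and the co-chaperone CHORDC1 (-0.76 ± 0.09). The list had a median of -0.22 (camera, Benjamini-Hochberg adjusted p = 0.00105, and adjusted p = 0.293 with an estimated correlation). Proteasome subunits had 0 that rose, 9 that fell and 22 that did not pass of 31, also 9 adjusted over the list alone. The members had a median of -0.13 (camera, Benjamini-Hochberg adjusted p = 2.57e-04, and adjusted p = 0.284 with an estimated correlation). Cholesterol genes had 2 that rose, 11 that fell and 13 that did not pass of 26, or 2 and 13 adjusted over the list alone. The median over the list was -0.25 (camera, Benjamini-Hochberg adjusted p = 0.00251, and adjusted p = 0.179 with an estimated correlation). With DESeq2 the falls were fewer, 12 of the DNA replication genes, 15 of the mitosis genes, 8 of the heat shock proteins and 3 of the cholesterol genes, and 0 heat shock proteins and 0 cholesterol genes rose.

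Matrix genes rose in footprints, 19 of 29 with 2 that fell and 8 that did not pass, or 21 and 2 adjusted over the list alone. These genes had a median of 0.71 (camera, Benjamini-Hochberg adjusted p = 1.61e-14, and adjusted p = 0.17 with an estimated correlation). FN1 (2.21 ± 0.11), the basement membrane collagens COL4A1 (1.13 ± 0.08) and COL4A2 (0.80 ± 0.08) and laminin LAMC1 (0.75 ± 0.09) are examples. Of 30 targets of ATF6 and XBP1, the unfolded protein response of the ER, 14 rose, 0 fell and 16 did not pass, or 16 and 0 adjusted over the list alone, such as the chaperones CALR (0.52 ± 0.07), HSP90B1 (0.47 ± 0.07) and PDIA3 (0.40 ± 0.07). The median was 0.30 (camera, Benjamini-Hochberg adjusted p = 1.82e-04, and adjusted p = 0.17 with an estimated correlation). In RNA this list did not pass, with 2 that rose and 2 that fell of 31 (camera, Benjamini-Hochberg adjusted p = 0.949). Collagen-modifying ER enzymes had 7 that rose, 1 that fell and 13 that did not pass of 21, the same adjusted over the list alone. Their median was 0.19 (camera, Benjamini-Hochberg adjusted p = 0.0147, and adjusted p = 0.317 with an estimated correlation), and the call was lost without footprint control replicate 2 (adjusted p = 0.0969). The prolyl hydroxylase subunits P4HB (0.49 ± 0.08) and P4HA1 (0.77 ± 0.13), the lysyl oxidase LOXL2 (0.60 ± 0.11) and the procollagen protease BMP1 (1.22 ± 0.19) rose. In RNA 4 of 23 rose and 1 fell (camera, Benjamini-Hochberg adjusted p = 0.897). Of 29 mesenchymal genes 13 rose, 5 fell and 11 did not pass, or 15 and 5 adjusted over the list alone, with TGFBI (0.90 ± 0.07) and CD44 (0.83 ± 0.08), and FN1 is a member of this list too. The list median was 0.29 (camera, Benjamini-Hochberg adjusted p = 2.57e-04, and adjusted p = 0.17 with an estimated correlation). In RNA 8 of 32 rose and 5 fell (camera, Benjamini-Hochberg adjusted p = 0.192), and with DESeq2 5 and 3. With DESeq2 9 targets of ATF6 and XBP1 rose, and 8 mesenchymal genes rose and 4 fell.

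Interferon response genes rose in footprints as well, 29 of 40 with 1 that fell and 10 that did not pass, the same adjusted over the list alone, such as SAMD9 (1.65 ± 0.16), the immunoproteasome subunit PSMB8 (1.18 ± 0.13) and IFI6 (1.63 ± 0.22). The list had a median of 0.72 (camera, Benjamini-Hochberg adjusted p = 1.4e-10, and adjusted p = 0.17 with an estimated correlation). Glycolysis and hypoxia genes had 16 that rose, 2 that fell and 14 that did not pass of 32, or 21 and 2 adjusted over the list alone. The members had a median of 0.39 (camera, Benjamini-Hochberg adjusted p = 1.7e-10, and adjusted p = 0.17 with an estimated correlation). Epithelial junction and keratin genes had 9 that rose, 3 that fell and 8 that did not pass of 20, or 10 and 3 adjusted over the list alone. The median over the list was 0.60 (camera, Benjamini-Hochberg adjusted p = 4.79e-07, and adjusted p = 0.17 with an estimated correlation). Inflammatory genes had 12 that rose, 4 that fell and 7 that did not pass of 23, or 13 and 4 adjusted over the list alone. These genes had a median of 0.51 (camera, Benjamini-Hochberg adjusted p = 5.83e-06, and adjusted p = 0.17 with an estimated correlation). CDH1 (1.55 ± 0.10), KRT18 (0.90 ± 0.06), C3 (1.57 ± 0.09) and the chemokine CXCL5 (0.68 ± 0.08) are among them. NRF2 targets had 18 that rose, 6 that fell and 10 that did not pass of 34, or 18 and 7 adjusted over the list alone, with ALDH1A1 (0.89 ± 0.05) the most abundant gene of both knockdown footprint libraries. The median was 0.22 (camera, Benjamini-Hochberg adjusted p = 1.82e-04, and adjusted p = 0.179 with an estimated correlation). Alveolar and airway genes had 4 that rose, 2 that fell and 3 that did not pass of 9, or 6 and 2 adjusted over the list alone. Their median was 0.67 (camera, Benjamini-Hochberg adjusted p = 0.0403, and adjusted p = 0.293 with an estimated correlation), and the call was lost without footprint control replicate 2 (adjusted p = 0.105) or footprint knockdown replicate 1 (adjusted p = 0.106). With DESeq2 16 interferon response genes rose and 0 fell, 8 inflammatory genes rose and 1 fell, 15 NRF2 targets rose and 3 fell, and 2 alveolar and airway genes rose and 2 fell.

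Lists that did not pass in RNA or footprints include the prolyl isomerases other than FKBP10. In RNA 0 of 31 rose and 2 fell, with a median of 0.01 and a mean of -0.02 (camera, Benjamini-Hochberg adjusted p = 0.629), and in footprints 1 of 28 rose and 5 fell (camera, Benjamini-Hochberg adjusted p = 0.191). The isomerases that fell in RNA were FKBP4 and FKBP14. The value of FKBP14 was -0.56 without RNA control replicate 1 and -0.46 without RNA control replicate 2. In footprints FKBP9 (0.47 ± 0.10), an ER relative of FKBP10, rose. The cytosolic isomerases FKBP4 (-0.42 ± 0.07), FKBP5 (-0.67 ± 0.15) and PPIA (-0.30 ± 0.06) fell in footprints. Targets of p53 had 4 that rose and 1 that fell of 27 in RNA (camera, Benjamini-Hochberg adjusted p = 0.721) and 5 and 1 of 26 in footprints (camera, Benjamini-Hochberg adjusted p = 0.943). Oxidative phosphorylation subunits had 3 and 2 of 57 in RNA and 8 and 2 of 57 in footprints, fatty acid synthesis genes 3 and 2 of 15 and 4 and 2 of 15, and proline metabolism genes 1 and 2 of 10 and 1 and 3 of 10. With DESeq2 the footprint counts were 1 and 3 for prolyl isomerases, 1 and 0 for p53 targets, 4 and 2 for oxidative phosphorylation, 3 and 2 for fatty acid synthesis and 1 and 0 for proline metabolism. With DESeq2 in RNA, proline metabolism had 1 and 1, fatty acid synthesis 3 and 1, oxidative phosphorylation 2 and 2, p53 targets 3 and 1 and heat shock proteins 1 and 4. Genes of the mitochondrial genome had 0 that rose and 2 that fell of 13 in RNA, and 4 were deep enough to test in footprints. Heat shock proteins in RNA had 2 that rose and 4 that fell of 23, with a median of -0.09 and a mean of 0.01 (camera, Benjamini-Hochberg adjusted p = 0.186). The median, the mean and the test differ in sign for several of these lists. In RNA they are the collagen-modifying enzymes, the prolyl isomerases, proline metabolism, fatty acid synthesis, oxidative phosphorylation, the mitochondrial genome, heat shock proteins and fibroblast markers. In footprints they are p53 targets, proline metabolism and fibroblast markers. Of the markers of other cell types, the macrophage-associated lysosomal protein CD68 rose in RNA (1.33 ± 0.10) and footprints (1.72 ± 0.16), and 3 further blood cell markers deep enough to test did not pass. Adjusted over the list alone, 2 blood cell markers rose in RNA and 1 in footprints. Of 6 fibroblast markers in RNA ACTA2 (0.96 ± 0.16) rose and 5 did not pass, and 2 endothelial markers did not pass. Adjusted over the list alone, 2 fibroblast markers and 1 endothelial marker rose in RNA. In footprints 0 of 5 fibroblast markers rose and 1 fell, the collagen COL1A1 (-0.42 ± 0.16, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0447), while 4 did not pass. Adjusted over the list alone 0 rose and 0 fell. COL1A1 was lost in 3 of the 4 fits with 1 library left out, without footprint control replicate 1, control replicate 2 or knockdown replicate 2, where adjusted p reached 0.673 and the value -0.19 (edgeR quasi-likelihood test, Benjamini-Hochberg), and it was lost with DESeq2, library totals, a mean count of 50 and 1 fit over all 8 libraries. The 1 endothelial marker tested in footprints did not pass, but rose adjusted over the list alone.

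**Figure D2:**
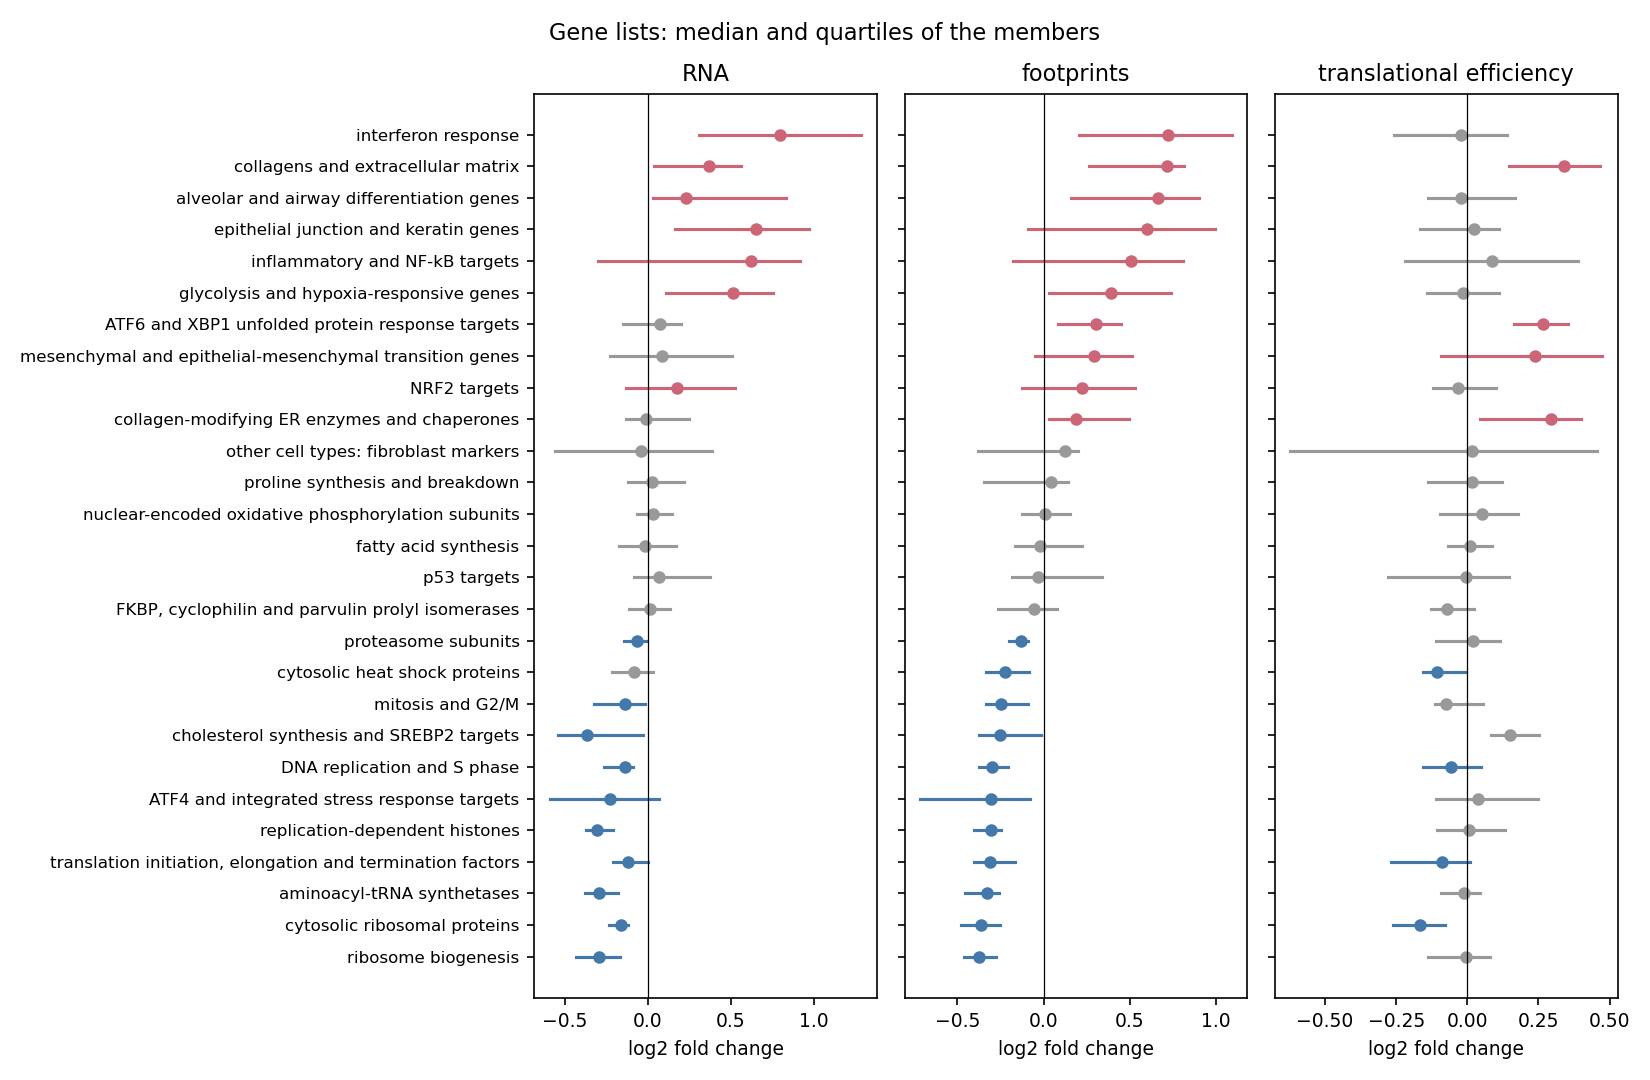
Median log2 fold change and quartiles of the members of each gene list in RNA, footprints and translational efficiency. Lists past the camera test at its preset correlation are in colour (red higher, blue lower). With an estimated correlation 0 lists passed in each comparison. Other scalings turn the sign of the median only for some grey lists.

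RNA and footprints mostly changed in the same direction. Among 11224 genes tested in both, 886 rose in both and 517 fell in both, where independent lists would give 193 and 133. A further 1558 were called in footprints alone and 1023 in RNA alone, and 16 were called in opposite directions. RNA and footprint fold changes correlated at 0.750 (Pearson) and 0.613 (Spearman), and of the 4000 genes called in either, 88.4% had the same sign. Leaving out 1 library gave a Pearson correlation of 0.528 to 0.729. USH1C (3.53 in RNA and 2.97 in footprints), CDH1 (1.23 and 1.55) and PSMA6 (-1.47 and -1.34) lie near the diagonal.

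**Figure D3:**
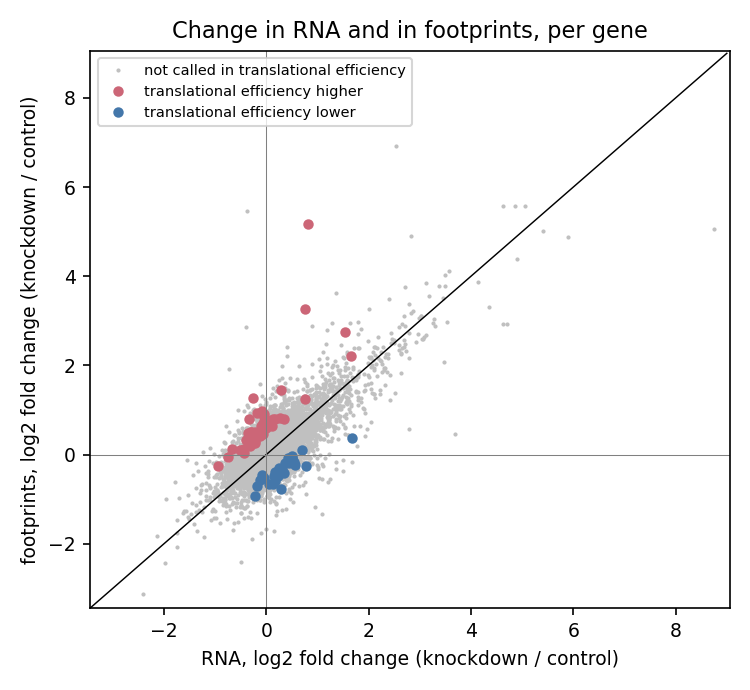
Log2 fold change of each gene in RNA and in footprints. The line marks equal change, and genes whose translational efficiency changed are coloured.

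Fewer genes passed the test in translational efficiency than in RNA or footprints. The ratio carries the spread of both kinds of library, with a standard error for FKBP10 of 0.21 against 0.12 in RNA and 0.16 in footprints. Simulated changes were also recovered less often there. The lower number therefore does not by itself show that few genes changed in translation. Values here are log2 fold changes of the ratio of footprints to RNA. Ferritin light chain FTL, whose mRNA carries an iron-responsive element, rose by 0.99 ± 0.11 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.80e-05), at 0.90 in footprints and -0.05 in RNA. TYMS (-0.74 ± 0.12), which makes thymidylate, and HNRNPD (-0.76 ± 0.14), which binds AU-rich mRNA elements, fell. The calls of FTL, TYMS, HNRNPD and the proteasome ATPase PSMC5 (-0.60 ± 0.11) held in all 8 fits with 1 library left out.

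Other rises in translational efficiency were RGS14 (2.60 ± 0.56), a regulator of G protein signalling with few footprints, the immunoproteasome subunit PSMB10 (1.58 ± 0.25), the mucin MUC13 (1.26 ± 0.27), the extracellular sulfatase SULF2 (1.20 ± 0.28), the receptor kinase ADRBK2 (1.19 ± 0.28), TMEM219 (1.17 ± 0.27), WBP1L (1.10 ± 0.27), the ER lectin ERLEC1 (0.93 ± 0.16) and MTMR12 (0.87 ± 0.17). Falls were PML (-1.26 ± 0.29), which organizes nuclear bodies, the keratin KRT84 (-1.07 ± 0.25), NAF1 (-0.99 ± 0.24), an assembly factor of box H/ACA particles, TOB1 (-0.74 ± 0.15), the ADP/ATP carrier SLC25A6 (-0.68 ± 0.15), the kinase MAP3K14 (-0.68 ± 0.14) and the spectrin SPTBN1 (-0.67 ± 0.16). PML rose in RNA (1.67) while its footprints did not pass (0.38, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0584). The call of PSMB10 was lost without footprint control replicate 1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0611). ERLEC1 was lost without footprint control replicate 1 (adjusted p = 0.154 by the same edgeR test with Benjamini-Hochberg adjustment) or footprint knockdown replicate 2 (0.298), and TOB1 without footprint control replicate 2 (0.0674) or footprint knockdown replicate 2 (0.087). Of the 32 named genes that passed, 25 were lost without footprint control replicate 1, 22 without footprint control replicate 2, 17 without footprint knockdown replicate 1, 24 without footprint knockdown replicate 2, 20 without RNA control replicate 1, 12 without RNA control replicate 2, 7 without RNA knockdown replicate 1 and 18 without RNA knockdown replicate 2. ADRBK2, WBP1L, PML and NAF1 were lost in 7 of these 8 fits, MUC13, SULF2, TMEM219, KRT84 and SPTBN1 in 6, RGS14, SLC25A6 and MAP3K14 in 5 and MTMR12 in 4. Without footprint knockdown replicate 2 the value of SULF2 moved to 0.59, that of WBP1L to 0.41 and that of KRT84 to -1.67, and without RNA knockdown replicate 2 that of PML moved to -0.83. With limma-voom RGS14, MUC13, SULF2, ADRBK2, TMEM219, WBP1L, MTMR12, PML, KRT84, NAF1, SLC25A6, MAP3K14 and SPTBN1 were lost. KRT84, NAF1, SPTBN1 and WBP1L were lost with library totals, SULF2, TMEM219 and WBP1L with a mean count of 50, and ADRBK2 and WBP1L with DESeq2 size factors.

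**Figure D4:**
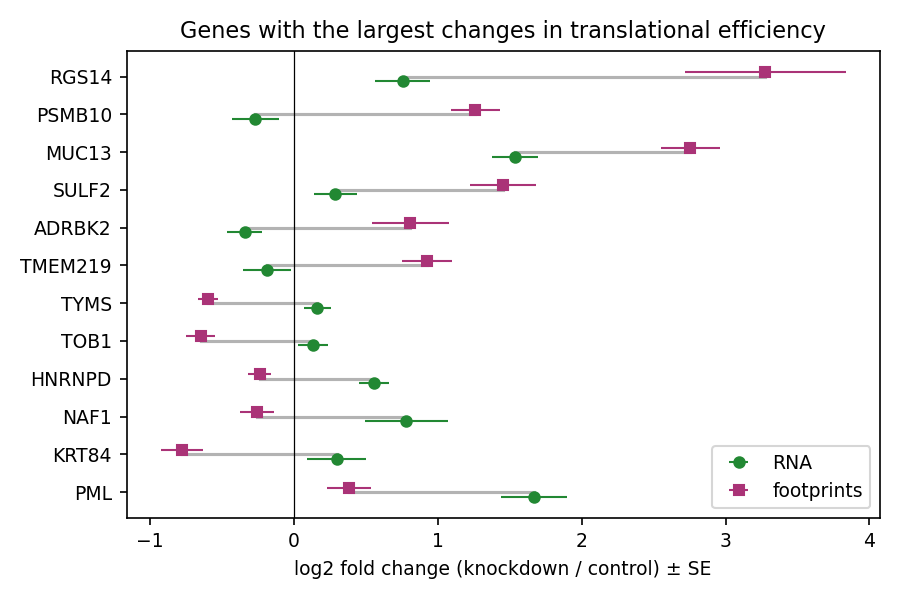
Log2 fold changes with standard errors in RNA and in footprints for the genes with the largest changes in translational efficiency that passed the test. The grey line between the symbols spans the difference of the separate fits.

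By the edgeR quasi-likelihood test 86 of 11224 genes changed in translational efficiency, 59 higher and 27 lower, and 1292 had an unadjusted p under 0.05. Of the 59 higher, 49 were higher in footprints and 21 lower in RNA, with medians of 0.69 in the ratio, 0.47 in footprints and -0.22 in RNA. Of the 27 lower, 18 were lower in footprints and 12 higher in RNA. The number depends on the libraries: it was 9 without footprint control replicate 1, 10 without footprint control replicate 2, 25 without footprint knockdown replicate 1, 18 without footprint knockdown replicate 2, 35 without RNA control replicate 1, 44 without RNA knockdown replicate 2 and 160 without RNA knockdown replicate 1. The split of 59 higher and 27 lower turned without each footprint library, to 1 and 8 without control replicate 1, 3 and 7 without control replicate 2, 7 and 18 without knockdown replicate 1 and 8 and 10 without knockdown replicate 2. The number was 31 with limma-voom and 156 without a filter. With DESeq2 size factors the split was 32 higher and 27 lower, and with a mean count of 50 it was 25 and 43.

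The list of ribosomal proteins lay lower in translational efficiency, although few members passed singly. Of 74 tested 0 rose, 2 fell and 72 did not pass, or 14 fell adjusted over the list alone. With limma-voom 0 fell, with library totals 0 and with DESeq2 10, and 23 had a fall at an unadjusted p under 0.05. The list median was -0.17 (camera, Benjamini-Hochberg adjusted p = 1.23e-10, and adjusted p = 0.259 with an estimated correlation). RPLP1 (-0.49 ± 0.12) and RPL11 (-0.40 ± 0.10) are the pair that fell, with adjusted p-values of 0.0168 to 0.187 and 0.0352 to 0.126 over the fits with 1 library left out (edgeR quasi-likelihood test, Benjamini-Hochberg). Of 51 translation factors 0 rose, 5 fell and 46 did not pass, or 7 fell adjusted over the list alone. The list had a median of -0.09 (camera, Benjamini-Hochberg adjusted p = 5.18e-06, and adjusted p = 0.2 with an estimated correlation). The poly(A)-binding protein PABPC1 (-0.53 ± 0.10) and the elongation factors EEF2 (-0.60 ± 0.13), EEF1G (-0.45 ± 0.11) and EEF1A1 (-0.35 ± 0.08) are among those that fell. PABPC1 was lost without footprint control replicate 2 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0513), EEF2 in 4 of the 8 fits with 1 library left out, and EEF1G and EEF1A1 in 6 each. DNA replication genes had 0 that rose, 1 that fell, TYMS, and 43 that did not pass of 44, also 1 adjusted over the list alone. The members had a median of -0.06 (camera, Benjamini-Hochberg adjusted p = 0.00602, and adjusted p = 0.259 with an estimated correlation). With limma-voom 3 translation factors fell, and RPLP1, RPL11 and EEF2 were lost. RPLP1, RPL11, EEF1G and EEF1A1 were lost with library totals. A block by culture, which pairs RNA and footprints of the same replicate number, ended the calls of RPLP1, RPL11, EEF2, EEF1G and EEF1A1.

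The lists of ER and matrix genes lay higher in translational efficiency, with few members that passed singly. Genes encoding a hydrophobic N-terminus also lay higher as a class, with a median of 0.19 against 0.01 in other genes. Whether these lists rose beyond that class was not tested, so their rise is not shown to be particular to them. Of 30 targets of ATF6 and XBP1, 0 passed in the edgeR test over all genes, 10 had a rise at an unadjusted p under 0.05, 2 rose with DESeq2 and 0 with limma-voom, and 8 rose adjusted over the list alone. The median over the list was 0.27 (camera, Benjamini-Hochberg adjusted p = 4.06e-06, and adjusted p = 0.117 with an estimated correlation). The values of CALR (0.44 ± 0.11), PDIA6 (0.43 ± 0.11) and PDIA4 (0.40 ± 0.11) lie above 0. Of 29 matrix genes 2 rose, LAMC1 (0.73 ± 0.12) and FN1 (0.60 ± 0.14), 0 fell and 27 did not pass, or 4 and 1 adjusted over the list alone. These genes had a median of 0.34 (camera, Benjamini-Hochberg adjusted p = 1.17e-05, and adjusted p = 0.259 with an estimated correlation). LAMC1 was lost without footprint control replicate 1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0506), footprint control replicate 2 (0.104) or footprint knockdown replicate 2 (0.0793), and FN1 in 7 of the 8 fits with 1 library left out. Of 29 mesenchymal genes FN1 rose and 28 did not pass, or 6 rose adjusted over the list alone. The median was 0.24 (camera, Benjamini-Hochberg adjusted p = 0.00602, and adjusted p = 0.2 with an estimated correlation), and the call was lost without footprint knockdown replicate 2 (adjusted p = 0.0947). Of 21 collagen-modifying ER enzymes 0 passed over all genes by edgeR, by DESeq2 or by limma-voom, 4 rose and 1 fell at an unadjusted p under 0.05, and 3 rose adjusted over the list alone. Their median was 0.29 (camera, Benjamini-Hochberg adjusted p = 0.00867, and adjusted p = 0.524 with an estimated correlation). That camera call was lost without footprint control replicate 2 (Benjamini-Hochberg adjusted p = 0.193), footprint knockdown replicate 1 (adjusted p = 0.127) or RNA knockdown replicate 1 (adjusted p = 0.128). Heat shock proteins had 0 of 22 that passed by edgeR, by DESeq2 or by limma-voom and 2 that fell at an unadjusted p under 0.05. The list median was -0.11 (camera, Benjamini-Hochberg adjusted p = 0.0143, and adjusted p = 0.524 with an estimated correlation), and the call was lost without RNA control replicate 1 (adjusted p = 0.156) or RNA knockdown replicate 1 (adjusted p = 0.175). FKBP9 (0.62 ± 0.14) was the only prolyl isomerase that rose of 28 tested, and its list did not pass (camera, Benjamini-Hochberg adjusted p = 0.463). FKBP9 was lost in 7 of the 8 fits with 1 library left out. FKBP9 and FN1 were both lost with DESeq2 size factors, a mean count of 50 and limma-voom. With limma-voom 1 matrix gene and 0 mesenchymal genes rose.

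The remaining lists did not pass in translational efficiency (camera, Benjamini-Hochberg). Adjusted p was 0.064 for mitosis, 0.244 for cholesterol synthesis, 0.4 for aminoacyl-tRNA synthetases, 0.473 for ribosome biogenesis, 0.511 for interferon response and for proteasome subunits, and 0.518 for glycolysis and hypoxia and for epithelial genes. It was 0.536 for p53 targets and for inflammatory genes, 0.831 for ATF4 targets and for proline metabolism, 0.942 for oxidative phosphorylation, fatty acid synthesis and alveolar genes, and 0.965 for NRF2 targets and histones in these camera tests with Benjamini-Hochberg adjustment. The median, the mean and the test differ in sign for proline metabolism, histones, NRF2 targets, epithelial genes, fatty acid synthesis, proteasome subunits and fibroblast markers. Among their members FTL and FTH1 (0.48 ± 0.12), the ferritin chains, and the histone gene HIST1H4E rose and PSMC5 fell. FTH1 and HIST1H4E were each lost in 7 of the 8 fits with 1 library left out, and without footprint knockdown replicate 1 the value of FTH1 moved to 0.25 and that of HIST1H4E from 0.52 to 0.31. Both were lost with DESeq2 size factors, a mean count of 50 and limma-voom, and FTH1 also with DESeq2.

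Proline content was compared because FKBP10 acts on proline bonds. Translational efficiency of the 2929 genes that encode 3 prolines in a row had a median of 0.02, against 0.04 in 8256 others, and did not pass (camera, Benjamini-Hochberg adjusted p = 0.706). The 1119 genes with the highest share of proline codons had a median of -0.02 against 0.04 and a mean difference of -0.09 (camera, Benjamini-Hochberg adjusted p = 0.0663, and adjusted p = 0.689 with an estimated correlation). Across genes the rank correlation of the share of proline codons with the change in translational efficiency was -0.01. In RNA (adjusted p = 0.357 for both sets) and in footprints (adjusted p = 0.837 for both) the camera tests with Benjamini-Hochberg adjustment did not pass either.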

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

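The lookup of opposite calls, and its repeat with libraries left out, were chosen after the result was seen. A difference between RNA and footprints marked 15 genes for a closer look. Each was called in opposite directions in RNA and footprints, and the interaction test passed. NCKAP5L was also opposite, but its interaction did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0662). In 11 genes RNA was lower and footprints higher. These are ERGIC1 (-0.30 in RNA, 0.41 in footprints and 0.74 in the ratio), TFDP1 (-0.30, 0.52 and 0.84), NOMO1 (-0.27, 0.46 and 0.76), MET (-0.27, 0.32 and 0.61), FAT1 (-0.28, 0.28 and 0.59), MTMR12 (-0.36, 0.47 and 0.87), STOML2 (-0.32, 0.20 and 0.56), B4GALT5 (-0.31, 0.39 and 0.73), THAP4 (-0.28, 0.37 and 0.69), ADRBK2 (-0.34, 0.81 and 1.19) and TMED3 (-0.33, 0.29 and 0.65). In 4 genes RNA was higher and footprints lower, among them HNRNPD (0.56, -0.24 and -0.76), PSMC5 (0.30, -0.33 and -0.60) and PABPC1 (0.37, -0.20 and -0.53). NOMO1 shares reads with its near-identical copies, so its value is uncertain.

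Of the 15 genes, 3 kept all of these calls without footprint control replicate 1, 2 without footprint control replicate 2, 3 without footprint knockdown replicate 1, 3 without footprint knockdown replicate 2, 4 without RNA control replicate 1, 8 without RNA control replicate 2, 8 without RNA knockdown replicate 1 and 3 without RNA knockdown replicate 2. The sign of the ratio was kept by all 15 in each of these fits. They were picked for their ratio in these same libraries, so a kept sign was nearly fixed in advance and is no separate support.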

How the results depend on the processing

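The alternatives were chosen before the data were examined, except the crossed pairing, the list tests with a library left out and the hydropathy settings, which were chosen after the result was seen. FKBP10 kept its direction and its call in RNA and footprints under every alternative. With 1 library left out its log2 fold change was -1.43 to -1.21 in RNA and -1.37 to -0.97 in footprints. Its ratio was not called in any fit, was -0.13 to 0.26 with 1 library left out, and changed sign without footprint control replicate 2 (-0.04), footprint knockdown replicate 1 (-0.13) and RNA knockdown replicate 1 (-0.02), and the cause was not tested. A fit with 1 library left out leaves a group with 1 sample, which is assumed to vary like the other groups.

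The count of genes changed in RNA, 2656 in the main analysis, was 1280 to 2499 with 1 library left out. In footprints, 2998 became 1716 to 2946, and 1372 with DESeq2. Without footprint knockdown replicate 2, 13 of the main calls had the opposite sign. For genes changed in translational efficiency, 86 became 9 to 160 with 1 library left out, 31 with limma-voom and 156 without a filter. A plain overlap, footprint calls without a same-direction RNA change at an unadjusted p under 0.05, gave 1217. Fewer samples are part of the fits with a library left out, and for the other differences the cause was not tested. The share of higher calls in footprints was 61.2% with library totals against 52.6%, in RNA 44.6% in 1 fit over all 8 libraries against 58.5%, and in translational efficiency 78.1% with library totals, 54.2% with DESeq2 size factors and 36.8% with a mean count of 50, against 68.6%. In translational efficiency more calls were lower than higher without each footprint library. The median log2 fold change over all genes there was 0.034 in the main fit, 0.053 with library totals and -0.0008 with DESeq2 size factors. It was -0.041 with a mean count of 50 and -0.087 to -0.061 without each footprint library. In RNA it was 0.0075, and -0.045 in 1 fit over all 8 libraries. Between library totals, TMM and DESeq2 size factors, which use the same libraries and genes, the share of higher calls in translational efficiency went with the median there. The other fits also changed the libraries, the genes or the model, so their balance cannot be ascribed to the scaling. The correlation of fold changes was 0.528 to 0.729 with 1 library left out, among them 0.705 without footprint control replicate 1, 0.695 without RNA control replicate 1 and 0.684 without RNA knockdown replicate 1, and 0.715 from the authors' RPKM.

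With a replicate block, 3098 genes changed in RNA, 3691 in footprints and 112 in translational efficiency, and 63 in translational efficiency with a block by culture. Beside the ribosomal proteins and elongation factors named above, the block by culture ended the calls of FN1, FTH1, NAF1, SPTBN1 and WBP1L. FKBP10 had -1.31, -1.23 and 0.09 with the replicate block, and 17, 21 and 8 lists passed, as without it. Samples of the same number hardly deviated together, with correlations of 0.0185 between the RNA groups, 0.0892 between the footprint groups, 0.0680 between RNA and footprints of control cells and -0.121 between those of knockdown cells. With the numbers of the knockdown pairs crossed, the block by culture gave 215 calls, 142 higher and 73 lower.

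With an estimated correlation between genes 0 of the 17 lists in RNA, 0 of 21 in footprints and 0 of 8 in translational efficiency passed, the smallest adjusted p being 0.205, 0.17 and 0.117 (camera, Benjamini-Hochberg). The estimate was under the preset for some lists, such as -0.0151 for glycolysis and hypoxia genes in RNA. Their unadjusted camera p still went from 3.63e-12 to 0.0151, so a higher correlation is not the reason there. In this setting camera rests on the few residual degrees of freedom of the fit, so a list that did not pass is not shown to be unchanged. With the preset correlation and 1 library left out, 15 to 17, 19 to 21 and 6 to 10 lists passed. Tests of proline content did not pass with an estimated correlation, with a mean count of 50 or with the share of proline codons as a continuous value, and were run in no other setting. The first knockdown footprint library is the shallowest, with 1645405 counts.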

Other observations

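The group of genes with very large rises and the hydropathy classes were chosen after the result was seen, as were the tests of hepatocyte and intestinal markers, of chromosomes and of PSMA6. In RNA 58 genes rose over 8-fold and 4 fell as far. Of the 58, 49 had a control mean under 1 CPM, and the median went from 0.135 CPM in controls to 3.14 CPM in knockdown cells. Examples are FABP1, a fatty acid binding protein of liver and gut (0.0350 to 4.72 CPM), S100A9, a calcium-binding protein of myeloid cells (0.112 to 5.04 CPM), VIL1, a microvillus protein (0.130 to 1.88 CPM), the complement regulator CFI (1.86 to 15.8 CPM) and DOCK8, an exchange factor (2.72 to 26.1 CPM). The immunoglobulin genes IGHG1 (0.0525 to 4.92 CPM) and IGHG3 (0 to 3.90 CPM), which are similar enough to share reads, are also among the 58. Of 22 blood cell markers 4 were deep enough to test in RNA, and 1 of these, CD68, rose, or 2 adjusted over the list alone.

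Genes encoding a hydrophobic N-terminus, the property of signal peptides and signal anchors, lay higher in translational efficiency. The 2032 such genes had a median of 0.19 against 0.01 in 9153 others, with 39 that rose and 3 that fell (camera p = 5.42e-08, and p = 0.00483 with an estimated correlation). The difference of these medians depends on the hydropathy threshold, at 0.0944 with 1.5, 0.178 with 2 and 0.227 with 2.5. Such genes make up 66.1% of the genes that rose, 11.1% of those that fell and 18.2% of those tested. In footprints the medians were 0.16 against -0.03. In RNA the class did not pass, with a median of 0.03. PRSS23 and ADAM9, and the NOMO genes, which share reads with each other, are among those whose ratio rose.

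The difference of 0.178 between these medians may reflect depth, sequence composition, recovery of membrane-bound ribosomes or translation at the ER in knockdown cells. It was 0.149 without the first knockdown footprint library (95% interval over resampled genes 0.126 to 0.171). It was 0.176 with a trend on coding length removed and 0.179 with a trend on GC content removed. So the shallow library, coding length and GC content, each taken singly, account for less than 50% of the difference. They were not removed together, so their joint share is not known. Resampling genes treats them as independent and does not measure the spread between libraries. With 1 library left out the difference was 0.142 (RNA control replicate 1) to 0.222 (footprint knockdown replicate 2). Genes with an internal hydrophobic segment alone lay 0.0664 above genes with neither (95% interval over resampled genes 0.0532 to 0.0801). This is above 0 but under the bound of 0.0892 set at 50% of the difference. Altered recovery of membrane-bound ribosomes and changed translation at the ER cannot be told apart here. A looser bound was tried for the recovery test once its value was known, and the original bound was restored.

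The 58 genes that rose over 8-fold could come from hepatocyte or intestinal cells in the knockdown cultures, and their spread over chromosomes was looked at too. The median rise over 12 hepatocyte markers was 0.125 CPM and over 12 intestinal markers 0.116 CPM, against 3.03 CPM over the 58 genes, although 5 and 3 of the markers rose by over 1 CPM. The chromosome with most of the 58 genes, chromosome 14, held 10.3% of them (95% interval 3.89% to 21.2%), and 21 chromosomes held at least 1. The markers as a set rose less than these genes, but the 58 were picked for their large rise in the same data. FABP1 and VIL1 are among both the intestinal markers and the 58, so a contribution from such cells is not excluded. An extra copy of a chromosome would not raise genes over 8-fold, so the share per chromosome could not decide on it. Cells of other types, blood cells among them, and descent of the knockdown cells from few cells were not tested for this group and stay open.

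PSMA6 RNA fell to 36.0% of control, farther than FKBP10, and might have been lost with a chromosome segment or have fallen with all proteasome subunits. The 13 tested genes within 1 Mb had a median of -0.0802, and the 30 other subunits a median of -0.0610. So neither a loss of most of this window nor a fall of all subunits accounts for it. A loss of PSMA6 alone or with few neighbours would leave that median unchanged and stays open. PSMA6 counts were 4553 and 3337 in control RNA and 920 and 1107 in knockdown RNA. A direct effect of the hairpin on PSMA6 was not tested, because the labels used here give no hairpin sequence.

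MTRNR2L8, a nuclear copy nearly identical to the mitochondrial large ribosomal RNA, had 10468 footprint counts in the first knockdown library against 110, 143 and 275 in the other footprint libraries, and 33 to 67 in RNA. Genes of chromosome 13 had a median of 0.14 in RNA (214 genes, 41 higher and 11 lower) and 0.16 in footprints (193 genes, 47 higher and 13 lower), the highest of the chromosomes, and did not pass in RNA (camera, Benjamini-Hochberg adjusted p = 0.687) or footprints (adjusted p = 0.1).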
